A study of Arabidopsis thaliana with 35 samples.

How the data were processed

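RNA of 35 samples, enriched guard cells or whole leaves of Arabidopsis thaliana, was hybridised by the authors to 1-colour (Cy3) Agilent arrays of 1 design with 45220 spots, 43803 of them for 43603 probes that are not controls. Per the file headers, the scanner files were made with Feature Extraction 9.5.3.1 and hold linear intensity values. The processed signal is background-subtracted and detrended within the array but not normalized between arrays, and the mean spot signal and local background median are raw intensity. Flags for spots well above background, saturated spots and outliers are other values, deposited as 0 or 1. The matrix deposited by the authors holds log2 values. Set against the scanner files, its columns were quantile-normalized mean signals without background subtraction, not centred by gene, with medians between 8.276 and 8.282. Each of the 35 columns was closest to its own array, and 8 of them had a rank correlation with the mean signal of 0.992 to 0.996 in place of 1, for a reason the files do not show. Replicate 4 of ABA was extracted with another protocol version, without surrogate values, and held 128 signals at or below 0. Scaled signals of all arrays were therefore given a floor at the highest of the lowest values of the other arrays, log2 of -8.30, which held 336 signals of this array. This floor was chosen after seeing the data.

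For the main analysis, log2 of the processed signal was taken minus the 75th percentile of each array. Control spots and spots flagged as outliers (5 to 162 per array) were left out, saturated spots (0 to 4 per array) were kept, and spots of 1 probe were averaged. A probe was kept if at least 1 group had it well above background on all of its arrays. Probes were named by the locus in the array files, and loci by the symbols of the reference. Of the probes, 38413 had a locus and 5190 had none, 873 listed more than 1 locus, and 28595 of the 29030 loci were in the reference, 10534 with a symbol. A gene was represented by its brightest passing probe, chosen before any test, which gave 25226 genes, 9835 with a symbol, with 483 values left empty by outlier flags.

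The 10 groups follow the labels. Tests used limma 3.58.1 in R 4.3.3 (data.table version 1.17.8, statmod 1.5.0), with lmFit and eBayes on all 35 arrays and a mean per group, so that all groups share 1 estimate of the spread. Contrasts compared guard cells with leaves, ABA with control spray, low with high humidity, slac1-3 with gl1-1 and ost1-2 with Ler, and the ABA contrast with the humidity contrast. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Before the data were examined, 24 gene lists with 357 members were fixed from general knowledge, of which 1 member was left out because the reference gives its symbol to another locus. They hold guard cell genes, stomatal ion transport, ABA synthesis, ABA breakdown and transport, ABA receptors, clade A PP2Cs, SnRK2 kinases and ABF factors, ABA-responsive genes, DREB and cold factors, jasmonate, salicylate and defence, touch and wounding, heat shock, aquaporins, starch and sugar, cell wall loosening, auxin response, the clock and stomatal development, and as markers of other cells light harvesting, Calvin cycle and photorespiration, epidermis and cuticle, trichomes and vasculature. Of the 15 guard cell genes, 8 are also on another list. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 24 lists.

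The genes named follow a rule also fixed before: the mutated gene, the 8 largest rises and 8 largest falls among called genes that have a symbol and no overlap between the groups, and up to 4 members of each list with the smallest adjusted p, from which examples are given. For the pair of ABA and humidity it takes the 8 genes called in both with the largest smaller change and the 8 with the smallest adjusted p for the difference. GL1 was not tested, since its probe did not pass the filter. A probe not well above background on any array of a group has a bound there. Its fold is then given as at least the ratio to the lowest signal well above background on each such array, or to the probe's own signal where higher. On simulated data, of 100 genes shifted 2-fold, 59 to 77 were called, and of 100 shifted 4-fold, 75 to 89, with 5 to 13 false calls among 24755 genes. Camera called the shifted list and 0 of 20 unshifted ones in each comparison, which does not test its preset correlation on real lists.

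Replicate numbers were checked for pairing by correlating the deviations of same-numbered arrays from their group means. For ABA and control spray all 4 pairs correlated (r from 0.179 to 0.442) and each array did so best with its own number, so these arrays were taken as paired, from the data and not from the labels. The other comparisons were not. Slides and scan days were tested as batches. Alternatives planned before were normexp background correction with an offset of 50 on the mean signal, quantile normalization and scaling to 7 spike-in probes (without 2 arrays that lack the spike-in signal, replicate 1 of ost1-2 and replicate 2 of slac1-3). They also took in no filter on dim probes, probes well above background on all arrays, the mean of a gene's probes and fits of the compared groups alone with and without a replicate block. Further ones were slide as a block (as a random block where each slide holds 1 group), trended and robust variances, array weights, the authors' values, and leaving out each replicate. Chosen after seeing the data were scan day as a block, fits within the scan day or slide that holds both groups, a fit without the 3 arrays with the highest share of probes well above background, which stand apart from their groups (replicate 4 of Col-0 guard cells, replicate 3 of slac1-3 and replicate 4 of ABA), a fit without replicate 3 of slac1-3 and gl1-1, high-humidity guard cells in place of untreated ones, and unsprayed gl1-1 in place of the control spray with slide as a block. Probes without a locus were left out of the comparisons.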

Results

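Transcript levels were measured on 35 one-colour Agilent arrays of Arabidopsis thaliana, 1 array per RNA sample, in 10 groups. Guard cell fractions, which are epidermal preparations enriched for the cell pair that borders each stomatal pore, came from untreated plants after 5 h of light. These were Col-0 (n = 4), gl1-1, a mutant without trichomes (n = 3), slac1-3, a mutant of the guard cell anion channel SLAC1 (n = 3, slac15 in the sample titles, so the allele is in doubt), Ler (n = 3) and ost1-2, a Ler mutant of the ABA-activated kinase OST1 (n = 2). Whole leaves of Col-0 (n = 4) served as the comparison tissue. Treated guard cell fractions came from gl1-1 leaves sprayed for 4 h with abscisic acid (50 µM in total, 25 µM of it the active form, n = 4) or with a control solution (n = 4), and from Col-0 plants kept for 4 h in air of 20 % relative humidity (n = 4) or above 85 % (n = 4, 80 % or above 80 % elsewhere in the record). Abscisic acid (ABA) is the hormone that closes stomata under water shortage. Between 68.2 and 93.8 % of the probes of an array were well above background, and the 75th percentile of the signal lay between 696 and 2270 intensity units.

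A gene is given with its locus at first mention, its fold difference, and its log2 fold change ± the standard error of the limma fit over the arrays of the groups compared. Each gene named as risen or fallen passed the test over all 25226 genes. Lists of genes fixed before the data were examined are given with the number of measured members that rose or fell (adjusted over all genes and, in parentheses, over the list alone) and with the camera set test, which compares a list with the other genes, at a preset correlation of 0.01 between genes and, in parentheses as estimated, at an estimated correlation. The scores in the next paragraph are mean log2 levels of a list, centred on all arrays, ± SD.

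Markers set the leaves apart from the 9 guard cell groups. The guard cell list scored -2.14 ± 0.10 in leaves (n = 4) and 0.39 ± 0.12 in untreated Col-0 guard cells (n = 4), with the other guard cell groups between -0.41 ± 0.18 (low humidity, n = 4) and 0.77 ± 0.12 (control spray, n = 4). The Calvin cycle and photorespiration list, typical of mesophyll, scored 1.60 ± 0.05 in leaves and -0.02 ± 0.07 in untreated Col-0 guard cells. Trichome genes scored highest in Ler (0.99 ± 0.30, n = 3) and ost1-2 (0.78 ± 0.14, n = 2), against -0.08 ± 0.23 in gl1-1 (n = 3). On average, an array correlated with the others of its group at r between 0.964 and 0.994. Replicate 3 of slac1-3 was closer to gl1-1 (mean r = 0.984) than to its own group (0.964), and replicate 3 of gl1-1 was closer to slac1-3 (0.981) than to its own (0.980). SLAC1 was at -3.08 and 0.85 on these arrays. Replicate 3 of slac1-3 had 93.8 % of its probes well above background, against 75.9 and 68.2 % in the other slac1-3 arrays. Replicate 4 of the untreated Col-0 guard cells (91.5 %) and replicate 4 of ABA (92.1 %) also stood above their groups.

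**Figure D1:**
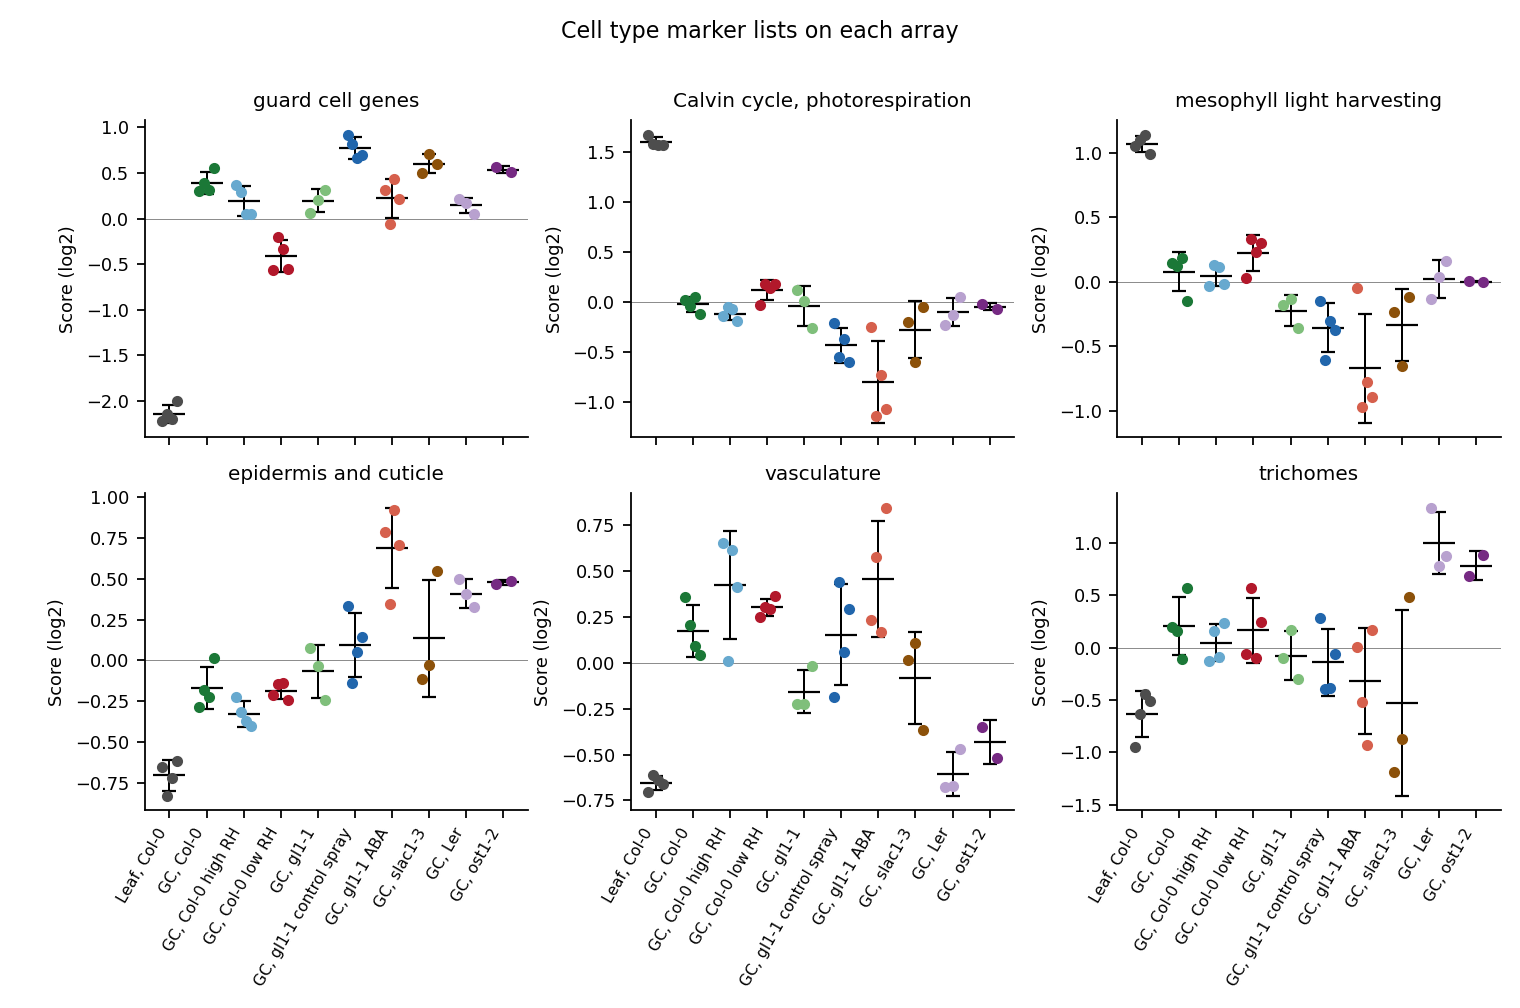
Mean log2 level of 6 marker lists on each array (points, centred on all 35 arrays) for the 10 groups, with the group mean as a bar and the SD as an error bar. The 4 leaf arrays lie apart from the guard cell arrays in the guard cell list (mean -2.14) and in the Calvin cycle list (mean 1.60).

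The comparison of guard cells with leaves of Col-0 asked which transcripts mark the guard cell fraction. Guard cell fractions held more transcript of several transporters of the stomatal pore. GORK, the outward potassium channel, was at 1.44 ± 0.21 (SD, n = 4) against -1.99 ± 0.20 (SD, n = 4) on the scaled log2 axis, a 10.7-fold rise (AT5G37500, 3.42 ± 0.15, adjusted p = 9.66e-16). The inward potassium channel gene KAT2 (AT4G18290, 7.27-fold, 2.86 ± 0.15), the cation exchanger gene CHX20 (AT3G53720, 6.91-fold, 2.79 ± 0.14), the proton pump gene AHA5 (AT2G24520, 5.98-fold, 2.58 ± 0.09) and the vacuolar malate channel gene ALMT6 (AT2G17470, 8.01-fold, 3.00 ± 0.15) rose as well. So did BLUS1 (AT4G14480, 9.40-fold, 3.23 ± 0.14), a kinase of blue-light signalling. Among single genes lower in guard cells than in leaves were the photosystem I subunit gene PSAH2 (AT1G52230, 6.15-fold lower, -2.62 ± 0.16) and the allene oxide cyclase genes AOC2 (AT3G25770, 12.7-fold lower, -3.67 ± 0.37) and AOC1 (AT3G25760, 7.29-fold lower, -2.87 ± 0.46).

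Every measured member of the guard cell list rose: 15 of 15 rose and 0 fell (15 and 0 over the list alone), median 2.77, camera adjusted p = 1.33e-12 (estimated, adjusted p = 0.0536). In the stomatal ion transport list, 15 of 24 rose and 2 fell (15 and 2 over the list alone), median 1.18, camera adjusted p = 9.33e-06 (estimated, adjusted p = 0.0536), and 6 of its members are also on the guard cell list. Among stomatal development genes, 6 of 8 rose and 0 fell (6 and 0 over the list alone), median 2.5, camera adjusted p = 0.00434 (estimated, adjusted p = 0.370). The transcription factor gene FAMA (AT3G24140, 6.80-fold, 2.77 ± 0.15), the peptide gene EPF1 (AT2G20875, 6.77-fold, 2.76 ± 0.28) and the receptor gene TMM (AT1G80080, 5.03-fold, 2.33 ± 0.31), which act in the stomatal lineage, were among them. Markers of other cell types were also higher in the guard cell fraction. In the epidermis and cuticle list, 15 of 23 rose and 1 fell (15 and 1 over the list alone), median 0.56, camera adjusted p = 0.0217 (estimated, adjusted p = 0.617). Examples are the wax genes CER2 (AT4G24510, 3.05-fold, 1.61 ± 0.12) and CER6 (AT1G68530, 2.11-fold, 1.08 ± 0.14). In the vasculature list, 7 of 14 rose and 0 fell (7 and 0 over the list alone), median 0.55, camera adjusted p = 0.0235 (estimated, adjusted p = 0.617). Examples are the phloem genes AHA3 (AT5G57350, 5.54-fold, 2.47 ± 0.13) and SUC2 (AT1G22710, 3.43-fold, 1.78 ± 0.14).

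Mesophyll genes fell. In the Calvin cycle and photorespiration list, 0 of 24 rose and 24 fell (0 and 24 over the list alone), median -1.62, camera adjusted p = 1.19e-15 (estimated, adjusted p = 0.190). Examples are PGK1 (AT3G12780, 4.12-fold lower, -2.04 ± 0.10) and HPR1 (AT1G68010, 5.06-fold lower, -2.34 ± 0.14). All 24 members were still well above background on each untreated Col-0 guard cell array. In the light harvesting list, 0 of 13 rose and 11 fell (0 and 12 over the list alone), median -0.94, camera adjusted p = 3.39e-05 (estimated, adjusted p = 0.370). Examples are LHCA2 (AT3G61470, 2.85-fold lower, -1.51 ± 0.19) and LHCB3 (AT5G54270, 2.61-fold lower, -1.38 ± 0.21). Among aquaporins, the water channels of plasma membrane and vacuole, 1 of 17 rose and 13 fell (1 and 14 over the list alone), median -0.89, camera adjusted p = 4.63e-05 (estimated, adjusted p = 0.328), and PIP2;2 (AT2G37170, 3.33-fold lower, -1.74 ± 0.13) and PIP2;1 (AT3G53420, 2.96-fold lower, -1.57 ± 0.13) fell. The camera test did not call the ABA synthesis, ABA breakdown, ABA receptors, PP2C, SnRK2 kinases, ABA-responsive genes, DREB and cold factors, jasmonate, salicylate, touch, heat shock, starch, cell wall loosening, auxin response, clock and trichomes lists (adjusted p from 0.0890 to 0.982). Median, mean and test differed in sign for DREB and cold factors, salicylate and starch. In the trichome list 6 of 10 rose and 2 fell (6 and 2 over the list alone), median 1.45, camera adjusted p = 0.348 (estimated, adjusted p = 0.791).

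The largest rises among genes with a symbol took in CHX12 (AT3G44910, 16.1-fold, 4.01 ± 0.62), ABCA4 (AT3G47750, 14.3-fold, 3.84 ± 0.18) and PIN5 (AT5G16530, 12.3-fold, 3.62 ± 0.33) beside UGT76E2 (AT5G59590, 11.3-fold, 3.5 ± 0.57), GDU5 (AT5G24920, 11.2-fold, 3.49 ± 0.27), FUS3 (AT3G26790, 11.2-fold, 3.48 ± 0.43) and ABCG27 (AT3G52310, 10.7-fold, 3.42 ± 0.26) (adjusted p from 3.44e-15 to 8.80e-06). CHX12 and UGT76E2 were each well above background on only 1 of the 4 leaf arrays. The largest falls took in the microRNA locus MIR846 (AT1G61226, 92.5-fold lower, -6.53 ± 0.61), the metacaspase gene MC9 (AT5G04200, 12.7-fold lower, -3.67 ± 0.56) and CLPB2 (AT4G14670, 11.2-fold lower, -3.49 ± 0.66), D6PK (AT5G55910, 6.92-fold lower, -2.79 ± 0.17) and PLDEPSILON (AT1G55180, 6.36-fold lower, -2.67 ± 0.50) (adjusted p from 2.55e-13 to 5.96e-05). In all, limma called 13594 of 25226 genes, 7933 higher and 5661 lower in guard cells, of which 3521 and 1884 differed at least 2-fold. The leaf arrays lay on a slide of their own, as did the untreated Col-0 guard cell arrays. With high-humidity guard cells, from another slide, in place of the latter, 14294 genes were called, all 34 named for this comparison among them. The medians were then 2.51 for guard cell genes and -1.69 for the Calvin cycle, and the epidermis list was not called (0.48, adjusted p = 0.105). Over the guard cell arrays of 9 other slides the guard cell list scored between -0.56 and 0.92, against a mean of -2.14 in leaves, so differences between slides of that size do not account for this list. For single genes the leaf slide and tissue cannot be told apart. With normexp background correction 6625 genes were called (3069 higher, 3556 lower) and CHX12, UGT76E2, MC9, CLPB2 and PLDEPSILON were not, quantile normalization ended the call of the light harvesting list (median -0.09), and spike-in scaling, which moved the median of all genes by 0.39, called 8194 higher and 1365 lower.

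The comparison of ABA with control spray in gl1-1 asked which guard cell genes respond to the hormone within 4 h. Genes of ABA responses and of ABA breakdown rose. HAI1, a protein phosphatase of the clade A type that inhibits ABA signalling, was at 2.88 ± 0.59 (SD, n = 4) after ABA and at -2.48 ± 1.43 (SD, n = 4) after the control spray, 41.2-fold higher (AT5G59220, 5.36 ± 0.46, adjusted p = 1.31e-09). The embryo-type protective protein genes EM6 (AT2G40170, 49.9-fold, 5.64 ± 0.72) and LEA7 (AT1G52690, 38.9-fold, 5.28 ± 0.58) and the ABA-inducible gene HVA22B (AT5G62490, 35.5-fold, 5.15 ± 0.35) rose too. CYP707A1 (AT4G19230, 16.6-fold, 4.05 ± 0.42), which encodes an enzyme that degrades ABA, and the ABA exporter gene ABCG25 (AT1G71960, 4.07-fold, 2.03 ± 0.19) also rose. The expansin genes EXPA8 (AT2G40610, 23.62-fold lower, -4.56 ± 0.61), EXPA5 (AT3G29030, 9.0-fold lower, -3.17 ± 0.23) and EXPB3 (AT4G28250, 5.94-fold lower, -2.57 ± 0.35) and the xyloglucan-modifying gene XTH31 (AT3G44990, 21.5-fold lower, -4.43 ± 0.34) fell. Without replicate 4 of the control spray HAI1 was 64.9-fold and LEA7 72.8-fold higher, and without replicate 1 of ABA EXPA8 was 50.4-fold lower.

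The largest rises among genes with a symbol also took in UGT74E2 (AT1G05680, 56.2-fold, 5.81 ± 0.63), XTH25 (AT5G57550, 53.9-fold, 5.75 ± 0.60), GSTU9 (AT5G62480, 40.9-fold, 5.35 ± 0.42) and LBD1 (AT1G07900, 36.3-fold, 5.18 ± 0.44) (adjusted p from 2.61e-10 to 5.56e-08). XTH25 was well above background on 1 of 4 control arrays and HVA22B on 2 of 4. The largest falls took in the cytokinin oxidase gene CKX4 (AT4G29740, 7.54-fold lower, -2.91 ± 0.33), the auxin-response gene SAUR26 (AT3G03850, 7.16-fold lower, -2.84 ± 0.37), EPF1 (5.48-fold lower, -2.46 ± 0.28) and the wall enzyme gene GH9C2 (AT1G64390, 5.46-fold lower, -2.45 ± 0.26), whose other probes gave between -2.59 and 0.11. In the list of ABA-responsive genes, 27 of 30 rose and 0 fell (28 and 0 over the list alone), median 2.47, camera adjusted p = 6.72e-22 (estimated, adjusted p = 0.0219). An example is the co-repressor-type gene AFP1 (AT1G69260, 16.9-fold, 4.08 ± 0.31). In the ABA breakdown and transport list, 8 of 11 rose and 0 fell (9 and 1 over the list alone), median 2.02, camera adjusted p = 9.06e-05 (estimated, adjusted p = 0.0219). Among clade A PP2C phosphatases, 7 of 9 rose and 0 fell (7 and 0 over the list alone), median 1.37, camera adjusted p = 1.95e-07 (estimated, adjusted p = 0.111). Among ABA receptors, 1 of 12 rose and 7 fell (1 and 8 over the list alone), median -0.38, camera adjusted p = 0.0188 (estimated, adjusted p = 0.360), and PYL4 (AT2G38310, 3.12-fold lower, -1.64 ± 0.23) and PYL2 (AT2G26040, 2.78-fold lower, -1.47 ± 0.21) fell.

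Guard cell and stomatal development genes were lower after ABA than after the control spray, but not clearly lower than in unsprayed plants. In the guard cell list, 2 of 15 rose and 7 fell (2 and 8 over the list alone), median -0.42, camera adjusted p = 0.00192 (estimated, adjusted p = 0.490). The transcription factor gene MYB60 (AT1G08810, 3.03-fold lower, -1.60 ± 0.15) and the receptor-like kinase gene GHR1 (AT4G20940, 3.91-fold lower, -1.97 ± 0.28), whose other probe gave 0.23, fell. In the stomatal development list, 0 of 8 rose and 5 fell (0 and 5 over the list alone), median -0.77, camera adjusted p = 0.00926 (estimated, adjusted p = 0.490). An example is FAMA (1.94-fold lower, -0.95 ± 0.15). The guard cell list scored 0.22 ± 0.21 after ABA (n = 4) and 0.19 ± 0.13 in unsprayed gl1-1 (n = 3), against 0.77 ± 0.12 after the control spray (n = 4). Against unsprayed gl1-1 with slide as a block neither list was called (medians 0.16 and -0.40, adjusted p = 0.979 and 0.321), nor was FAMA (-0.33). Mesophyll markers moved the same way: in the Calvin cycle list 1 of 24 rose and 10 fell (1 and 17 over the list alone), median -0.43, camera adjusted p = 0.00192 (estimated, adjusted p = 0.548). Examples are FBA1 (AT2G21330, 2.09-fold lower, -1.07 ± 0.19) and GAPB (AT1G42970, 1.42-fold lower, -0.51 ± 0.12), whose values overlapped between the sprays. In the epidermis and cuticle list 9 of 23 rose and 3 fell (12 and 3 over the list alone), median 0.28, camera adjusted p = 0.0188 (estimated, adjusted p = 0.548). With spike-in scaling this median was -0.40, where that of all genes was -0.618. The wax synthesis genes CER1 (AT1G02205, 13.3-fold, 3.74 ± 0.29) and MYB96 (AT5G62470, 3.45-fold, 1.79 ± 0.15) rose. In a fit of these 8 arrays alone the epidermis list was called (adjusted p = 0.0279) and GAPB was not (0.0952). With the replicate number, which pairs the arrays, as a block as well, GAPB was called and the list was not (adjusted p = 0.0672). Of the cell wall loosening list, 2 of 12 rose and 4 fell (3 and 6 over the list alone), median -0.40, camera adjusted p = 0.161 (estimated, adjusted p = 0.560). The camera test did not call the stomatal ion transport, ABA synthesis, SnRK2 kinases, DREB and cold factors, jasmonate, salicylate, touch, heat shock, aquaporins, starch, cell wall loosening, auxin response, clock, light harvesting, trichomes and vasculature lists (adjusted p from 0.0526 to 0.916).

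In all, limma called 7973 genes, 3644 higher and 4329 lower after ABA, of which 1440 and 613 differed at least 2-fold. A fit of these 8 arrays alone called 4501 genes, and 4667 with the replicate number as a block as well, 2679 higher and 1988 lower. The spike-in scaling moved the median of all genes by -0.68 and turned the split to 718 higher and 10313 lower, and 4043 genes were called with normexp background correction. The control arrays lay on a slide of their own, while the ABA arrays shared theirs with unsprayed gl1-1. Against these, with slide as a block, 8669 genes were called. Of the 3644 rises and 4329 falls, 2512 and 2968 were called the same way and 39 and 74 the other way. HAI1 was at 4.74 (adjusted p = 5.30e-08) and the ABA-responsive list at a median of 2.44 (adjusted p = 1.25e-23), so slide alone does not account for these. For calls not repeated there the control slide and the spray cannot be told apart. The control arrays and 2 of the 4 ABA arrays shared a scan day, within which 8012 genes were called.

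The comparison of low with high humidity in Col-0 asked how guard cells in dry air differ from those in humid air. ABA-responsive genes were higher and ABA receptor genes lower in dry than in humid air. Rises and falls in dry air are given relative to humid air throughout. LEA7 (31.6-fold, 4.98 ± 0.58) and LEA4-5 (AT5G06760, 13.3-fold, 3.73 ± 0.45), which encode late embryogenesis abundant proteins, rose, as did RD20 (AT2G33380, 9.32-fold, 3.22 ± 0.25), which encodes a calcium-binding dehydration protein at 3.63 ± 0.14 (SD, n = 4) in dry and 0.41 ± 0.26 (SD, n = 4) in humid air (adjusted p = 2.31e-09). The receptor gene PYL6 (AT2G40330, 14.2-fold lower, -3.83 ± 0.43) fell (adjusted p = 7.00e-07). The factor genes BHLH100 (AT2G41240, 12.6-fold lower, -3.66 ± 0.89), bHLH39 (AT3G56980, 10.9-fold lower, -3.45 ± 0.71), bHLH38 (AT3G56970, 7.85-fold lower, -2.97 ± 0.66) and BHLH101 (AT5G04150, 7.58-fold lower, -2.92 ± 0.51) fell as well (adjusted p from 0.000250 to 0.00592).

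Other large rises were those of LTP3 (AT5G59320, 16.9-fold, 4.08 ± 0.53), BAM5 (AT4G15210, 14.5-fold, 3.86 ± 0.80) and ATGA2OX1 (AT1G78440, 13.8-fold, 3.78 ± 0.40), which encode a lipid transfer protein, a beta-amylase and a gibberellin oxidase. VSP2 (AT5G24770, 11.4-fold, 3.51 ± 1.17) rose with adjusted p = 0.0476, a call that 7 of the alternative settings did not keep and that ended without replicate 1, 3 or 4 of low or 1, 2 or 3 of high humidity (2.85 to 3.84, adjusted p from 0.0550 to 0.162). Other large falls were those of the calcium sensor gene SOS3 (AT5G24270, 5.92-fold lower, -2.57 ± 0.17), NAC004 (AT1G02230, 5.45-fold lower, -2.45 ± 0.49) and the phosphatase gene PEPC1 (AT1G17710, 5.39-fold lower, -2.43 ± 0.38), which was well above background on 2 of the 4 low-humidity arrays and turned to 0.30 with normexp background correction. LEA7 and LEA4-5 were each well above background on 2 of the 4 high-humidity arrays.

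In the list of ABA-responsive genes, 23 of 30 rose and 0 fell (26 and 0 over the list alone), median 1.54, camera adjusted p = 5.56e-31 (estimated, adjusted p = 0.00796). An example is AFP3 (AT3G29575, 7.80-fold, 2.96 ± 0.27), beside RD20. Among clade A PP2C phosphatases, 6 of 9 rose and 0 fell (7 and 0 over the list alone), median 0.64, camera adjusted p = 3.71e-07 (estimated, adjusted p = 0.0640). In the ABA synthesis list, 3 of 10 rose and 0 fell (4 and 0 over the list alone), median 0.40, camera adjusted p = 0.000175 (estimated, adjusted p = 0.00923). Examples are NCED3 (AT3G14440, 2.62-fold, 1.39 ± 0.21), the dioxygenase of the committed step, and ABA1 (AT5G67030, 2.05-fold, 1.04 ± 0.11). Among ABA receptors, 1 of 12 rose and 6 fell (1 and 7 over the list alone), median -0.42, camera adjusted p = 1.16e-06 (estimated, adjusted p = 0.00981). In the DREB and cold list 4 of 10 rose and 0 fell (6 and 0 over the list alone), median 0.93, camera adjusted p = 0.000183 (estimated, adjusted p = 0.0530). In the jasmonate list 15 of 22 rose and 0 fell (17 and 0 over the list alone), median 1.35, camera adjusted p = 5.57e-11 (estimated, adjusted p = 0.0821). In the touch and wounding list 3 of 10 rose and 0 fell (4 and 0 over the list alone), median 0.82, camera adjusted p = 0.00149 (estimated, adjusted p = 0.308).

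Aquaporins rose in dry air: 9 of 17 rose and 0 fell (10 and 1 over the list alone), median 0.50, camera adjusted p = 1.74e-09 (estimated, adjusted p = 0.0403). PIP2;3 (AT2G37180, 9.05-fold, 3.18 ± 0.25) and PIP2;2 (3.93-fold, 1.97 ± 0.13) of the plasma membrane and TIP2;2 (AT4G17340, 4.02-fold, 2.01 ± 0.15) of the vacuole were the clearest (adjusted p from 2.07e-10 to 2.31e-09). Guard cell genes fell: 0 of 15 rose and 9 fell (0 and 11 over the list alone), median -0.57, camera adjusted p = 1.74e-09 (estimated, adjusted p = 0.0403). The anion channel gene ALMT12 (AT4G17970, 2.99-fold lower, -1.58 ± 0.18) and FAMA (1.89-fold lower, -0.92 ± 0.15) were among them. In the stomatal ion transport list 1 of 24 rose and 9 fell (2 and 11 over the list alone), median -0.27, camera adjusted p = 0.00170 (estimated, adjusted p = 0.0915), where AHA5 (2.24-fold lower, -1.16 ± 0.09) fell and the vacuolar malate transporter gene TDT (AT5G47560, 3.41-fold, 1.77 ± 0.15) rose. The Calvin cycle list was higher by preset correlation alone: 3 of 24 rose and 0 fell (3 and 0 over the list alone), median 0.19, camera adjusted p = 0.00135 (estimated, adjusted p = 0.542). Examples are CAT2 (AT4G35090, 2.62-fold, 1.39 ± 0.18) and FBA2 (AT4G38970, 1.48-fold, 0.56 ± 0.15), the latter not called without high-humidity replicate 1 (0.46, adjusted p = 0.0639). In the starch and sugar list 3 of 12 rose and 1 fell (3 and 1 over the list alone), median 0.23, camera adjusted p = 0.0170 (estimated, adjusted p = 0.0821). Examples are SUS3 (AT4G02280, 3.36-fold, 1.75 ± 0.20) and BAM1 (AT3G23920, 1.92-fold, 0.94 ± 0.13). In the auxin list 4 of 9 rose and 0 fell (6 and 0 over the list alone), median 0.62, camera adjusted p = 0.000218 (estimated, adjusted p = 0.0868). The camera test did not call the ABA breakdown, SnRK2 kinases, salicylate, heat shock, cell wall loosening, clock, stomatal development, light harvesting, epidermis, trichomes and vasculature lists (adjusted p from 0.114 to 0.799). Median, mean and test differed in sign for clock and epidermis.

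In all, limma called 3087 genes, 1621 higher and 1466 lower in dry air, of which 604 and 262 differed at least 2-fold. Each humidity lay on a slide of its own, scanned on 1 day, so slide and humidity cannot be told apart. The count was 1145 with normexp background correction, which also ended the calls of PYL6, bHLH39, bHLH38, BHLH101 and NAC004 and of the Calvin cycle and starch lists, 471 with spike-in scaling (shift of the median of all genes -0.18), 1517 with slide as a random block and 5873 with array weights.

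**Figure D2:**
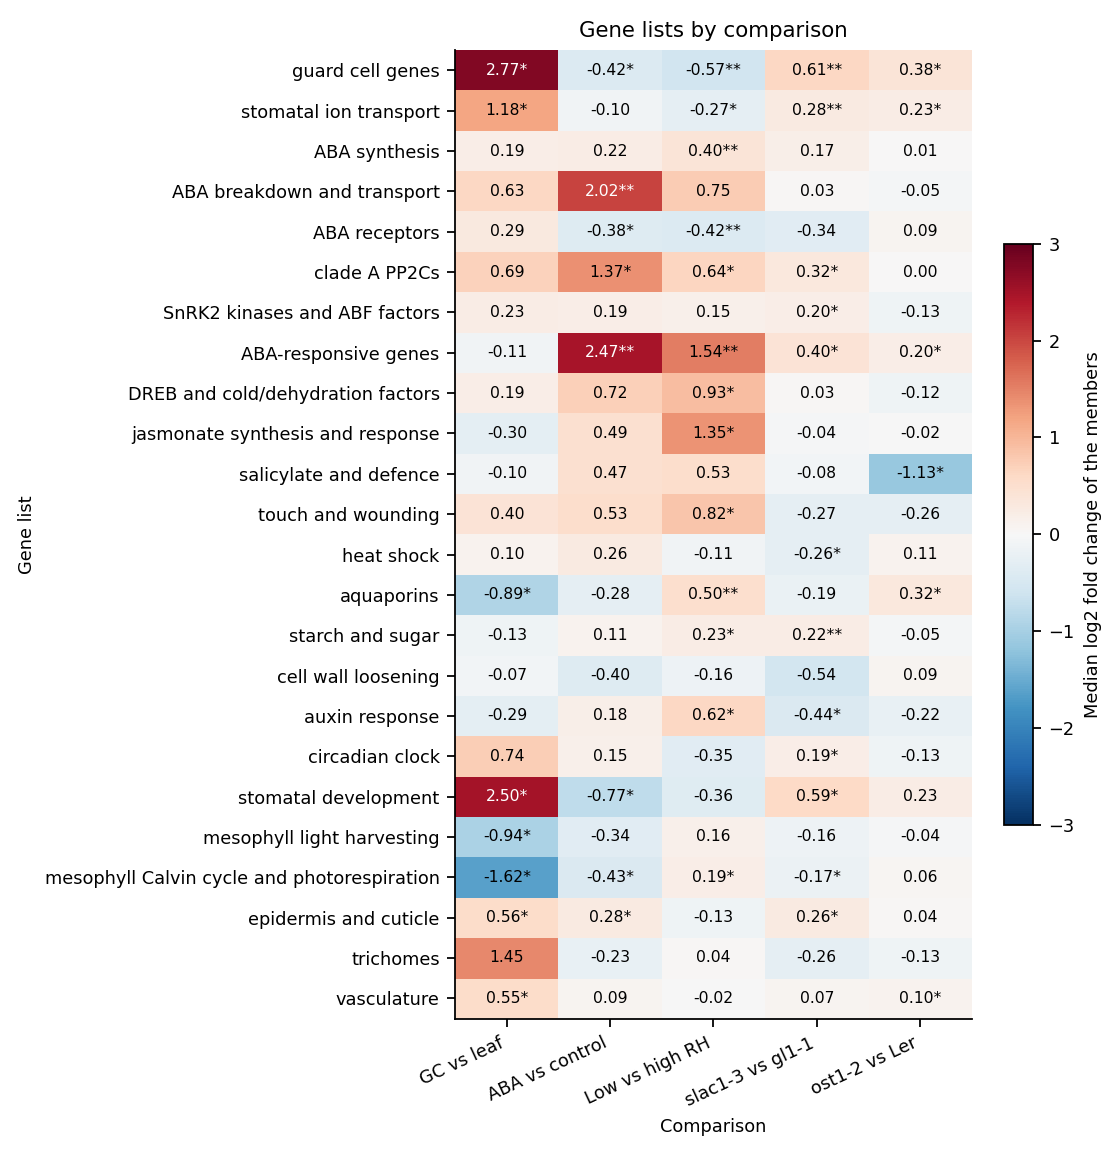
Median log2 fold change (colour, clipped at 3 in either direction) of the 24 gene lists in the 5 comparisons of groups, where 1 star marks a list called by camera with the preset correlation and 2 stars a list called with the estimated correlation too. The guard cell list is at 2.77 against leaves, -0.42 after ABA and -0.57 in dry air.

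Setting the ABA response beside the humidity response asked how far dry against humid air acts like the hormone in guard cells. Genes that rose in both include LEA7 (38.9-fold after ABA, 31.6-fold in dry air), the lipid transfer protein gene LTP3 (19.6-fold and 16.9-fold), the wax ester synthase gene WSD1 (AT5G37300, 9.19-fold and 10.1-fold) and the kinase gene MAPKKK18 (AT1G05100, 12.1-fold and 7.26-fold). AFP1 rose 16.9-fold and 7.85-fold, DAA1 (AT1G64110) 6.80-fold and 6.86-fold, and the heat shock factor gene HSFA6A (AT5G43840) 6.96-fold and 6.76-fold. HAI1 rose 41.2-fold after ABA and 7.92-fold in dry air, and this difference was called (2.38 ± 0.65, adjusted p = 0.0104), though not with spike-in scaling, which moved the median difference of all genes by -0.50. Without replicate 4 of the control spray LEA7 rose 72.8-fold and LTP3 30.9-fold after ABA, and the HAI1 difference was 3.03. Against unsprayed gl1-1 with slide as a block, the HAI1 difference was not called (1.75, adjusted p = 0.0681) and that of LEA7 was (3.76, adjusted p = 0.00178).

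The ABA contrast was measured in gl1-1 and the humidity contrast in Col-0, on other slides and scan days, so genotype and batch cannot be told apart from treatment where the responses differ. Of the aquaporin genes, TIP2;2 fell after ABA (-1.25) and rose in dry air (2.01), a difference of -3.26 ± 0.21 (adjusted p = 8.08e-11). PIP2;2 (-0.72 and 1.97) and PIP2;3 (-1.60 and 3.18) did the same, as did the methyl-cycle genes SAHH2 (AT3G23810, -1.24 and 1.65) and MS2 (AT3G03780, -0.56 and 1.60), though MS2 was not called after ABA against unsprayed gl1-1 (-0.22). PMAT1 (AT5G39050) rose by 2.99 after ABA and was at 0.13, not called, in dry air. HAM4 (AT4G36710) rose by 1.34 after ABA and changed by -0.39 in dry air, a call that ended without low-humidity replicate 2 or high-humidity replicate 3 or 4 (-0.37 to -0.36, adjusted p from 0.0524 to 0.0583). SOS3 fell in dry air (-2.57), and its value of 0.45 after ABA, called over all arrays, was not called in a fit of these 8 arrays alone (adjusted p = 0.0964) or with the replicate block as well (adjusted p = 0.144, over its alternatives and left-out replicates 1.99e-05 to 0.819). For these 8 genes the difference had adjusted p from 8.08e-11 to 2.93e-08.

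Lists were also tested on the difference, the ABA response minus the humidity response, where a member called positive or negative responded higher or lower to ABA than to dry air. Aquaporins lay lower: 1 of 17 were positive and 10 negative (1 and 10 over the list alone), median -0.71, camera adjusted p = 3.56e-07 (estimated, adjusted p = 0.193). The ABA breakdown and transport list lay the other way: 6 of 11 were positive and 0 negative (7 and 0 over the list alone), median 1.5, camera adjusted p = 0.00135 (estimated, adjusted p = 0.135). The PP2C list did too: 4 of 9 were positive and 0 negative (4 and 0 over the list alone), median 0.89, camera adjusted p = 0.0130 (estimated, adjusted p = 0.657). In the ABA-responsive list 9 of 30 were positive and 1 negative (10 and 1 over the list alone), median 0.43, camera adjusted p = 0.0458 (estimated, adjusted p = 0.728). With spike-in scaling this median was -0.07, where that of all genes was -0.454. In the jasmonate list 1 of 22 were positive and 2 negative (1 and 2 over the list alone), median -0.85, camera adjusted p = 0.0458 (estimated, adjusted p = 0.728). Mesophyll lists had a lower difference by preset correlation alone. In the Calvin cycle list 0 of 24 were positive and 8 negative (0 and 15 over the list alone), median -0.60, camera adjusted p = 1.29e-06 (estimated, adjusted p = 0.657). In the light harvesting list 0 of 13 were positive and 0 negative (0 and 0 over the list alone, 0 and 3 at an unadjusted p under 0.05 in limma), median -0.47, camera adjusted p = 0.0130 (estimated, adjusted p = 0.657). Of the epidermis list 9 of 23 were positive and 2 negative (11 and 3 over the list alone), median 0.49, camera adjusted p = 0.0134 (estimated, adjusted p = 0.657), with a median of -0.02 under spike-in scaling, also above all genes.

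Across genes, the fold changes of both treatments correlated at Pearson's r = 0.314 and Spearman's rho = 0.230, where genes are not independent replicates. The same direction was called in 1226 genes, 695 higher and 531 lower in both, where 234 and 252 would arise among independent genes (Fisher's exact test, one-sided, p = 1.14e-184 and 2.15e-73). These p-values do not measure chance between arrays. In 375 genes the calls were opposite, and the difference itself was called in 5028 genes, 2480 higher and 2548 lower after ABA. Fits of the compared groups alone called 990 genes the same way, and 780 with the replicate number as a block as well. Within the scan day that held both sprays r was 0.292. With normexp background correction r was 0.118, 464 genes were called the same way and 2026 differed. Spike-in scaling gave 269 (92 higher, 177 lower) and 1285 (211 higher, 1074 lower), and slide as a random block 630 and 2993.

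The comparison of slac1-3 with gl1-1 asked how the loss of the anion channel alters untreated guard cells. The mutated gene fell: SLAC1 (AT1G12480, probe at chromosome 1, 4257311 to 4257370 on the ath1 build named by the array) was at -2.80 ± 0.61 (SD, n = 3) in slac1-3 and 0.69 ± 0.17 (SD, n = 3) in gl1-1, 11.2-fold lower (-3.49 ± 0.24, adjusted p = 5.18e-10). Other guard cell genes were higher in slac1-3, among them BLUS1 (2.69-fold, 1.42 ± 0.16), ALMT12 (2.25-fold, 1.17 ± 0.20) and OST1 (AT4G33950, 1.76-fold, 0.82 ± 0.15). The cytokinin-activating enzyme gene LOG5 (AT4G35190, 5.40-fold, 2.43 ± 0.41), the transcription factor genes MYB74 (AT4G05100, 4.86-fold, 2.28 ± 0.30) and MYB102 (AT4G21440, 3.71-fold, 1.89 ± 0.24) and the wax gene CER1 (4.17-fold, 2.06 ± 0.33) rose as well (adjusted p from 5.48e-05 to 0.00162).

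The remaining largest rises were those of BOR4 (AT1G15460, 4.47-fold, 2.16 ± 0.47), BOR5 (AT1G74810, 3.94-fold, 1.98 ± 0.33) and GAUT12 (AT5G54690, 3.44-fold, 1.78 ± 0.27), which encode borate transporters and a wall glycosyltransferase, and the flavonol synthase gene FLS1 (AT5G08640, 2.93-fold, 1.55 ± 0.24). LOG5 and BOR4 were each well above background on 2 of 3 gl1-1 arrays. The floral repressor gene FLC (AT5G10140, 28.6-fold lower, -4.84 ± 1.17), with adjusted p = 0.0363, led the falls among genes with a symbol and no overlap, but its values spread from -3.43 to -0.56 in gl1-1 and from -5.38 to -0.01 after ABA. That of slac1-3 replicate 1 lay at the floor of -8.30. The fall was 17.7-fold and 47.1-fold without replicates 1 and 3 of slac1-3, and 16.9-fold and 45.6-fold without replicates 2 and 3 of gl1-1. FLC was well above background on 1 of 3 slac1-3 arrays, as were MLP34 (AT1G70850, 8.38-fold lower, -3.07 ± 0.67) and PIN8 (AT5G15100, 3.79-fold lower, -1.92 ± 0.41). LCV1 (AT2G20130, 2.81-fold lower, -1.49 ± 0.35), MEE47 (AT4G00950, 2.72-fold lower, -1.44 ± 0.26), PUB22 (AT3G52450, 2.45-fold lower, -1.29 ± 0.33) and CSLA14 (AT3G56000, 1.96-fold lower, -0.97 ± 0.20) completed the falls (adjusted p from 0.00347 to 0.0464). Calls ended without slac1-3 replicate 1 (FLC, MLP34, PIN8, LCV1, PUB22 and CSLA14), slac1-3 replicate 2 (FLC, MLP34, PIN8, LCV1 and PUB22), gl1-1 replicate 1 (FLC, PIN8, LCV1, MEE47, PUB22, CSLA14 and BOR4), gl1-1 replicate 2 (FLC, LCV1 and PUB22) or gl1-1 replicate 3 (MLP34 and PUB22), with adjusted p from 0.0522 to 0.265. MLP34 was 14.8-fold lower without replicate 3 of slac1-3. With spike-in scaling PIN8, LCV1, MEE47, PUB22 and CSLA14 were at 1.09 to 1.51, still below the median of all genes (2.503).

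In the guard cell list 6 of 15 rose and 1 fell (12 and 1 over the list alone), median 0.61, camera adjusted p = 3.72e-13 (estimated, adjusted p = 0.0218). In the ion transport list 5 of 24 rose and 1 fell (12 and 1 over the list alone), median 0.28, camera adjusted p = 1.02e-08 (estimated, adjusted p = 0.0137). Examples are AHA5 (1.89-fold, 0.92 ± 0.10) and NHX1 (AT5G27150, 1.85-fold, 0.89 ± 0.14), which encode a proton pump and a vacuolar exchanger. In the starch and sugar list 2 of 12 rose and 0 fell (2 and 0 over the list alone), median 0.22, camera adjusted p = 0.00170 (estimated, adjusted p = 0.0418). Examples are BAM1 (1.79-fold, 0.84 ± 0.15) and SUS3 (2.31-fold, 1.21 ± 0.24). The ABA-responsive list also moved up as a set: 1 of 30 rose and 0 fell (2 and 0 over the list alone), median 0.40, camera adjusted p = 2.60e-06 (estimated, adjusted p = 0.216). The member called was RAB18 (AT5G66400, 2.56-fold, 1.36 ± 0.22). In the stomatal development list 1 of 8 rose and 0 fell (2 and 0 over the list alone), median 0.59, camera adjusted p = 0.000214 (estimated, adjusted p = 0.181). The member called was SCRM (AT3G26744, 1.49-fold, 0.58 ± 0.12), whose other probe gave -0.87. Among epidermis and cuticle markers 2 of 23 rose and 0 fell (4 and 0 over the list alone), median 0.26, camera adjusted p = 6.11e-06 (estimated, adjusted p = 0.181). An example is CER2 (1.69-fold, 0.76 ± 0.14), beside CER1. In the clock list 1 of 11 rose and 0 fell (1 and 0 over the list alone), median 0.19, camera adjusted p = 0.00501 (estimated, adjusted p = 0.119). An example is GI (AT1G22770, 1.48-fold, 0.56 ± 0.14). In the SnRK2 kinase list 1 of 14 rose and 0 fell (2 and 0 over the list alone), median 0.20, camera adjusted p = 0.00170 (estimated, adjusted p = 0.181). Calls ended without slac1-3 replicate 1 (GI), slac1-3 replicate 2 (GI), gl1-1 replicate 1 (GI, SCRM and SUS3) or gl1-1 replicate 2 (GI), with adjusted p from 0.0856 to 0.191.

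The camera test also called 4 lists in slac1-3 with no member past the test. In the PP2C list 0 of 9 rose and 0 fell (2 and 0 over the list alone, 2 and 0 at an unadjusted p under 0.05 in limma), median 0.32, camera adjusted p = 0.0106 (estimated, adjusted p = 0.370). In the auxin list 0 of 9 rose and 0 fell (0 and 2 over the list alone, 0 and 3 at an unadjusted p under 0.05 in limma), median -0.44, camera adjusted p = 0.00501 (estimated, adjusted p = 0.216). In the heat shock list 0 of 13 rose and 0 fell (0 and 4 over the list alone, 0 and 5 at an unadjusted p under 0.05 in limma), median -0.26, camera adjusted p = 0.0366 (estimated, adjusted p = 0.370). In the Calvin cycle list 0 of 24 rose and 0 fell (0 and 0 over the list alone, 0 and 2 at an unadjusted p under 0.05 in limma), median -0.17, camera adjusted p = 0.0228 (estimated, adjusted p = 0.598). The calls of these 4 lists ended without the 3 arrays that stand apart. With spike-in scaling the last 3 were at 1.96, 2.26 and 2.52, and all genes at 2.503. The camera test did not call the ABA synthesis, ABA breakdown, ABA receptors, DREB and cold factors, jasmonate, salicylate, touch, aquaporins, cell wall loosening, light harvesting, trichomes and vasculature lists (adjusted p from 0.0580 to 0.886). Median, mean and test differed in sign for ABA breakdown, jasmonate and salicylate.

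In all, limma called 270 genes, 219 higher and 51 lower in slac1-3, and 4059 passed at an unadjusted p under 0.05. A fit of the 6 arrays alone called 0 genes with limma, 2000 at an unadjusted p under 0.05, and the arrays of these genotypes shared no slide or scan day. The count was 3706 without replicate 3 of slac1-3, 140 without replicate 2 of slac1-3 and 65 without replicate 1 of gl1-1. It was 59 with normexp background correction, 428 with quantile normalization, 23651 with spike-in scaling (23650 higher, 1 lower, without slac1-3 replicate 2, which lacks the signal) and 166 with slide as a random block. It was 1646 from the authors' values, 6543 with array weights (1201 higher, 5342 lower) and 4192 without the 3 arrays that stand apart (391 higher, 3801 lower). Without both arrays closer to the other genotype, replicate 3 of slac1-3 and of gl1-1, it was 4353 (440 higher, 3913 lower).

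The comparison of ost1-2 with Ler asked how the loss of the kinase alters untreated guard cells, with 2 mutant arrays. Among genes with a symbol and no overlap, LEA7 (70.3-fold, 6.14 ± 0.75) was the largest rise, at 5.78 ± 0.00 (SD, n = 2) against -0.36 ± 0.47 (SD, n = 3) (adjusted p = 1.74e-05). LEA4-5 (20.9-fold, 4.38 ± 0.59), RD29B (AT5G52300, 7.72-fold, 2.95 ± 0.55) and HVA22B (5.23-fold, 2.39 ± 0.46) rose as well. The largest fall was that of MRD1 (AT1G53480, 31.0-fold lower, -4.96 ± 0.38) (adjusted p = 1.23e-08). The transcription factor genes WRKY38 (AT5G22570, 14.8-fold lower, -3.89 ± 0.80) and NAC004 (9.16-fold lower, -3.20 ± 0.63) and the chaperone gene BIP3 (AT1G09080, 8.62-fold lower, -3.11 ± 0.84) fell too. OST1 itself, a point mutant in this line, was 1.68-fold higher (probe at chromosome 4, 16274732 to 16274791, 0.75 ± 0.17, adjusted p = 0.0176), and its other probes gave between 0.06 and 0.71. Calls ended without ost1-2 replicate 1 (HVA22B, WRKY38, NAC004, BIP3 and OST1), ost1-2 replicate 2 (BIP3), Ler replicate 1 (BIP3), Ler replicate 2 (WRKY38, BIP3 and OST1) or Ler replicate 3 (BIP3 and OST1), with adjusted p from 0.0559 to 0.424. WRKY38 was 25.6-fold lower without replicate 1 of Ler.

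The other large rises were those of ST4B (AT1G13420, 10.6-fold, 3.40 ± 0.73), LOG5 (10-fold, 3.33 ± 0.46), HSFA6A (6.94-fold, 2.79 ± 0.38) and DAA1 (5.28-fold, 2.4 ± 0.40) (adjusted p from 9.09e-05 to 0.0115). scpl31 (AT1G11080, at least 5.12-fold lower), LUP5 (AT1G66960, at least 3.49-fold lower), NAC095 (AT5G41090, at least 6.90-fold lower) and WRKY51 (AT5G64810, at least 2.98-fold lower) were not well above background on either ost1-2 array, so their folds are bounds, taken against the lowest signal well above background (adjusted p from 0.00227 to 0.0457). WRKY51 was well above background on 2 of 3 Ler arrays. In the guard cell list 2 of 15 rose and 0 fell (6 and 0 over the list alone), median 0.38, camera adjusted p = 6.57e-08 (estimated, adjusted p = 0.147). An example is BLUS1 (2.06-fold, 1.05 ± 0.18), beside OST1. In the ion transport list 3 of 24 rose and 0 fell (6 and 1 over the list alone), median 0.23, camera adjusted p = 4.07e-06 (estimated, adjusted p = 0.0735). Examples are NHX1 (1.69-fold, 0.76 ± 0.15) and AHA5 (1.40-fold, 0.48 ± 0.11). In the ABA-responsive list 3 of 30 rose and 0 fell (5 and 0 over the list alone), median 0.20, camera adjusted p = 3.29e-05 (estimated, adjusted p = 0.594). An example is RAB18 (2.5-fold, 1.32 ± 0.24), beside LEA4-5 and RD29B. Calls ended without ost1-2 replicate 1 (ST4B, scpl31, LUP5, NAC095, WRKY51, NHX1, AHA5 and RAB18), ost1-2 replicate 2 (ST4B, LUP5, WRKY51 and AHA5), Ler replicate 1 (LUP5 and WRKY51), Ler replicate 2 (LUP5, WRKY51 and AHA5) or Ler replicate 3 (WRKY51 and AHA5), with adjusted p from 0.0534 to 0.404.

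The salicylate and defence list was lower as a set: 0 of 16 rose and 0 fell (0 and 7 over the list alone, 0 and 9 at an unadjusted p under 0.05 in limma), median -1.13, camera adjusted p = 0.000152 (estimated, adjusted p = 0.526). Its members NIMIN1 (AT1G02450, -3.26 ± 0.88, adjusted p = 0.0512) and ICS1 (AT1G74710, -0.92 ± 0.26, adjusted p = 0.0606) were not called, though without replicate 1 of Ler both were (-4.02 and -1.21), as was ICS1 without replicate 3 (-1.04). Among aquaporins 0 of 17 rose and 0 fell (0 and 0 over the list alone, 3 and 0 at an unadjusted p under 0.05 in limma), median 0.32, camera adjusted p = 1.62e-05 (estimated, adjusted p = 0.321), and PIP2;2 was at 0.41 ± 0.17 (adjusted p = 0.227). The vasculature list was also called: 0 of 14 rose and 0 fell (0 and 0 over the list alone, 0 and 0 at an unadjusted p under 0.05 in limma), median 0.10, camera adjusted p = 0.0241 (estimated, adjusted p = 0.664). The list was not called within the slide that held both genotypes (median 0.02) or with scan day as a block (median -0.004). The camera test did not call the ABA synthesis, ABA breakdown, ABA receptors, PP2C, SnRK2 kinases, DREB and cold factors, jasmonate, touch, heat shock, starch, cell wall loosening, auxin response, clock, stomatal development, light harvesting, Calvin cycle, epidermis and trichomes lists (adjusted p from 0.0675 to 0.966). Median, mean and test differed in sign for ABA synthesis, ABA breakdown, ABA receptors, PP2C, DREB and cold factors, jasmonate, heat shock, starch, clock, light harvesting and trichomes.

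In all, limma called 489 genes, 167 higher and 322 lower in ost1-2, of which 98 and 223 differed at least 2-fold. Within the slide that held 1 ost1-2 and 3 Ler arrays, which is the fit without replicate 1 of ost1-2, 96 genes were called (54 higher, 42 lower), with the spread of the lone array taken from the other groups. With slide as a block it was 117 and with scan day as a block 173, while array weights gave 4415 (1058 higher, 3357 lower) and a fit without the 3 arrays that stand apart 1396 (258 higher, 1138 lower). Without replicate 2 of ost1-2 the count was 308, and without replicate 1 or 2 of Ler 254 or 238. The split turned to 218 higher and 180 lower with quantile normalization, and 27 genes were called with normexp background correction (18 higher, 9 lower). Spike-in scaling, for which replicate 1 of ost1-2 lacks the signal, gave 15 (13 higher, 2 lower), beside the 96 without that array.

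**Figure D3:**
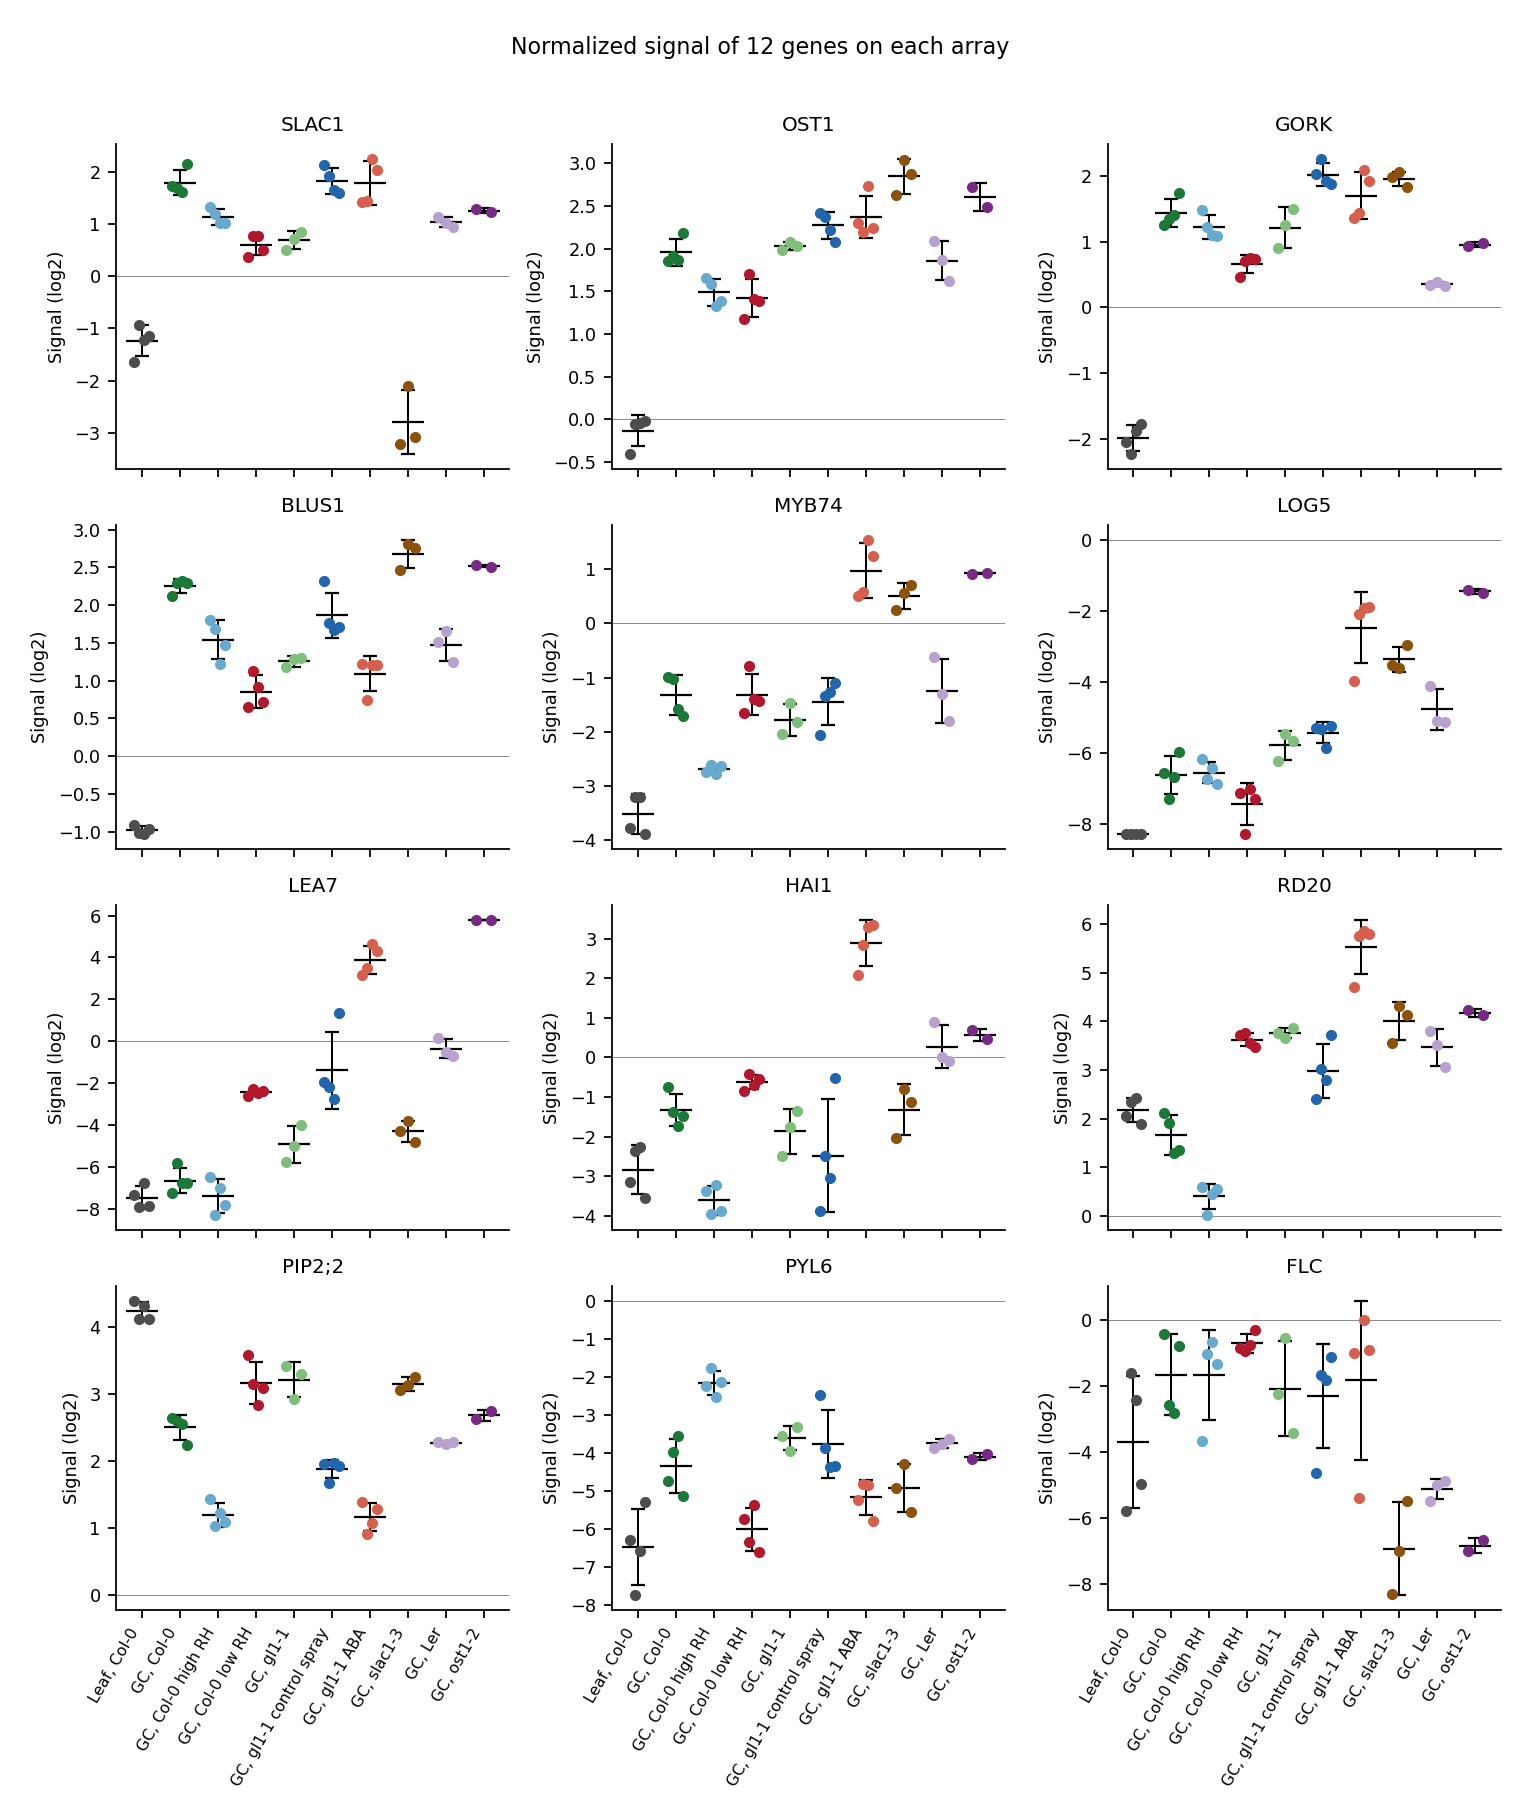
Scaled log2 level of 12 genes on each array (points) by group, with the group mean as a bar and the SD as an error bar. SLAC1 lies between -3.21 and -2.10 in slac1-3 and between 0.51 and 0.85 in gl1-1.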

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

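The tests on share of guard cells, leaf material and slide are given under the other observations, where those chosen after the results were seen are named. An array is listed here where it lay farther from the other 3 of its group than Dixon's 95 % limit for the gap over the range allows, which chance alone gives in about 1 of 20 groups. This held for 13 of 264 groups of gene values, 5 of 144 groups of list scores and 5 of 60 groups of array measures. Values are scaled log2 levels unless a unit is given.

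Among untreated Col-0 guard cells, BLUS1 was at 2.12 in replicate 1 (2.29 to 2.32 in the others). KAT2 was at 0.84 in replicate 4 of the same group (others 0.39 to 0.46). TMM was at 0.39 there (others 0.74 to 0.80). After ABA, HVA22B was at 0.23 in replicate 3 (others -0.65 to -0.58). EXPA8 was at 0.32 in ABA replicate 1 (others -4.33 to -3.71). PMAT1 was at 4.71 in ABA replicate 2 (others 3.88 to 3.95). After the control spray, SOS3 was at -1.12 in replicate 1 (others -1.33 to -1.32). HAM4 was at 2.72 on that array (others 2.97 to 3.01). In high humidity, HAI2 (AT1G07430) was at -3.92 in replicate 2 (others -3.29 to -3.18). HAM4 was at 1.71 on the same array (others 2.03 to 2.08). In low humidity, TDT was at 1.36 in replicate 3 (others 1.66 to 1.70). SAHH2 was at 4.47 on that array (others 4.24 to 4.26). MAPKKK18 was at -1.90 in low-humidity replicate 2 (others -2.91 to -2.74).

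Of the list scores, auxin response was at -0.40 in replicate 1 of the untreated Col-0 guard cells (others -0.08 to -0.04). The same list was at 0.29 in control spray replicate 1 (others -0.20 to -0.15). The Calvin cycle list was at 1.67 in leaf replicate 1 (others 1.57 to 1.58). Stomatal ion transport was at -1.26 on that array (others -1.16 to -1.15). Touch and wounding genes were at -1.12 in replicate 2 of the untreated Col-0 guard cells (others -0.08 to 0.09). The share of probes well above background was 91.5 % in replicate 4 of the untreated Col-0 guard cells (others 77.4 to 79.7 %), 92.1 % in ABA replicate 4 (others 85.3 to 86.3 %) and 71.5 % in high-humidity replicate 2 (others 77.4 to 78.6 %). ABA replicate 4 also had 1 saturated spot, against 0 in the others, and 128 signals at or below 0, against 0.

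Probes without a locus, which no comparison used, also differed between groups. Of 3977 such probes, 1589 were called between guard cells and leaves (980 higher, 609 lower), 543 after ABA (324 higher, 219 lower) and 195 in low humidity (128 higher, 67 lower). Between genotypes, 3 were called in slac1-3 (2 higher, 1 lower) and 60 in ost1-2 (5 higher, 55 lower).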

How the results depend on the processing

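Settings chosen after seeing the data were those named as such above. The list tests with a block, of compared groups alone or a left-out replicate were too. Of 3964 values of named genes under planned settings, 3606 kept direction and side of the threshold, 304 lost the call, 19 gained it, 26 changed sign without a call and 9 reversed. Under the added settings it was 460 of 494, with 25, 3, 5 and 1. Of 330 list medians 306 kept their call under planned settings, 21 lost it and 3 reversed, and under added ones 212 kept it and 13 lost it. With an estimated correlation 10 of 55 called lists stayed called. Where not said otherwise, the cause was not tested.

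Across the 12 planned settings other than left-out replicates, counts ranged from 6625 to 15043 for guard cells against leaves, 4043 to 11031 for ABA, 471 to 5873 for humidity, 0 to 23651 for slac1-3 and 0 to 4415 for ost1-2. Normexp background correction gave 6625, 4043, 1145, 59 (56 higher, 3 lower) and 27 genes in that order, 464 called the same way, r = 0.118 and 2026 differing, and PEPC1 reversed to 0.30 in low humidity. Quantile normalization gave 428 in slac1-3, and 218 higher and 180 lower in ost1-2. Spike-in scaling, by its construction, adds 1 constant per array and so moved the median of all genes (by 0.39, -0.68, -0.18, 2.59 and 0.24 in that order). It gave 471 for humidity, 23651 (23650 higher, 1 lower) for slac1-3, 15 (13 higher, 2 lower) for ost1-2 on 1 ost1-2 array (96 without the other array alone), 269 called the same way (92 higher, 177 lower), 1285 differing (211 higher, 1074 lower), 8194 higher and 1365 lower in guard cells against leaves, and 718 higher and 10313 lower after ABA. Under it, with that constant, SOS3 after ABA reversed to -0.23, and in slac1-3 PIN8 to 1.15, LCV1 to 1.41, MEE47 to 1.41, PUB22 to 1.09 and CSLA14 to 1.51. Against the median of all genes (-0.618 and 2.503) SOS3 stayed above and the other 5 below. In slac1-3 the direction of the camera test also reversed for ABA-responsive genes (median 2.92, adjusted p = 0.935), PP2Cs (2.83, adjusted p = 0.891) and the Calvin cycle (2.52, adjusted p = 0.0261), although the medians of the ABA-responsive and PP2C lists stayed above that of all genes. The authors' values gave 1646 for slac1-3, and 237 higher and 151 lower for ost1-2, with the DAA1 difference reversed to 0.95. The mean of a gene's probes reversed SCRM in slac1-3 to -0.15, since its probes differ in direction.

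Fits of the compared groups alone gave 4501 for ABA and 0 for slac1-3 (limma, 2000 at an unadjusted p under 0.05). With the replicate block as well, they gave 4667 for ABA, 780 called the same way (990 without the block), 0 for slac1-3 (1271 unadjusted) and 0 for ost1-2 (5190 unadjusted), 10738 for guard cells against leaves, 2352 for humidity, 4121 differing and r = 0.314. In the paired ABA comparison SOS3 was called in neither fit (adjusted p = 0.0964 and 0.144), GAPB not without the block (adjusted p = 0.0952) and the epidermis list not with it (adjusted p = 0.0672, and 0.0279 without). No other gene or list named for it lost its call, and with the block the AFP1 difference became called. The other comparisons share only a number, with deviations that correlated at -0.390 to 0.004, -0.120 to 0.063, -0.649 to -0.123 and -0.022 to 0.094, and of them only in ost1-2 and Ler did each pair correlate best with its own number. Slide as a block gave 1517, 166 and 117 for humidity, slac1-3 and ost1-2, 630 called the same way and 2993 differing (correlation within slides 0.119). Array weights gave 5873, 6543 and 4415. Scan day as a block gave 173 for ost1-2. Without the 3 arrays that stand apart it was 4192 for slac1-3 and 1396 for ost1-2, and without replicate 3 of slac1-3 and gl1-1 4353. Unsprayed gl1-1 as the baseline for ABA, with slide as a block, gave r = 0.249 and a DAA1 difference of 1.29, and ended the calls of the guard cell and stomatal development lists.

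Leaving out 1 replicate gave 12734 to 13155 genes for guard cells against leaves, 6750 to 8513 for ABA, 2351 to 2571 for humidity, 65 to 3706 for slac1-3, 96 to 503 for ost1-2, 955 to 1371 called the same way, r from 0.279 to 0.346 and 4061 to 5823 differing. Single arrays moved the slac1-3 count to 65 (gl1-1 replicate 1), 140 (slac1-3 replicate 2) and 3706 (slac1-3 replicate 3), and the ost1-2 count to 254 (Ler replicate 1) and 238 (Ler replicate 2). The share of probes well above background, 68.2 to 93.8 %, limits folds of dim genes, and the folds of scpl31, LUP5, NAC095 and WRKY51 in ost1-2 are bounds.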

Other observations

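The comparison of control spray with unsprayed plants, the replacement of baselines, the test on mesophyll after ABA, the splits for the pair of treatments that part every pair of replicates and the tests on slide and scan day of the guard cell list were chosen after the results were seen. The control spray went with large changes in gl1-1 guard cells against unsprayed plants (n = 4 and 3). The jasmonate-inducible genes VSP2 (5.11 ± 1.26, 34.5-fold, adjusted p = 0.00546) and VSP1 (AT5G24780, 32.7-fold) rose, as did the cold factor gene CBF3 (AT4G25480, 15.6-fold), the clock gene PRR5 (AT5G24470, 15.2-fold), LEA7 (11.7-fold) and the RNA-binding protein gene GRP7 (AT2G21660, 10.1-fold). The morning clock genes LHY (AT1G01060, 8.90-fold lower) and RVE1 (AT5G17300, 6.91-fold lower) fell. The bHLH factor genes BHLH100 (15.2-fold lower), BHLH101 (10.9-fold lower) and bHLH39 (8.49-fold lower) fell here as they did in dry air. Without replicate 4 of the control spray VSP2 rose 18.6-fold, VSP1 18.1-fold and LEA7 6.24-fold, and without its replicate 1 VSP2 rose 66.9-fold and VSP1 61.1-fold. Without replicate 2 of gl1-1 VSP2 rose 21.6-fold and VSP1 was not called (4.33, adjusted p = 0.0720), and without its replicate 3 they rose 57.5-fold and 53.9-fold. In all, limma called 3633 genes (1754 higher, 1879 lower), 2280 without replicate 1 of gl1-1, and 3200 within the scan day both groups shared. Unsprayed plants were taken after 5 h of light, and the labels do not give the hours of light of sprayed ones, so spray and time of day cannot be told apart.

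By list, aquaporins fell after the control spray (0 of 17 up and 14 down, median -1.10, camera adjusted p = 1.84e-12, adjusted p = 0.0267 with an estimated correlation). Heat shock genes fell (0 up and 8 down of 13, median -0.96, adjusted p = 5.27e-08 and 0.0291). Starch and sugar genes rose (7 up and 0 down of 12, median 0.80, adjusted p = 2.82e-08 and 0.000470). Guard cell genes rose by preset correlation (8 up and 0 down of 15, median 0.61, adjusted p = 4.30e-08), but not with an estimated one (adjusted p = 0.0663). Markers of other cells moved by preset correlation too: the Calvin cycle list fell (median -0.32, adjusted p = 0.000155), and the epidermis list (0.14, adjusted p = 0.0139) and the vasculature list (0.21, adjusted p = 0.0264) rose, each with adjusted p = 0.493 by estimated correlation. A preset call alone also held for rises of the DREB list (6 up and 0 down of 10, median 1.40, adjusted p = 9.73e-05 and 0.0538), of ABA-responsive genes (10 up and 2 down of 30, median 0.53, adjusted p = 0.000597 and 0.446), of the jasmonate list (median 0.50, adjusted p = 0.00336 and 0.493), ion transport (0.19, adjusted p = 0.00365 and 0.172), stomatal development (0.59, adjusted p = 0.00792 and 0.375) and the clock (1.53, adjusted p = 0.0126 and 0.147), and for a fall of cell wall loosening (-0.75, adjusted p = 0.0139 and 0.340). The genotypes slac1-3 and ost1-2 shared 59 raised genes, where 1.45 would arise among independent genes (Fisher's exact test, one-sided, p = 1.91e-80), among them BLUS1, OST1, AHA5, NHX1, RAB18 and LOG5. Both genotypes lowered 2 genes, where 0.651 would arise among independent genes (Fisher's exact test, one-sided, p = 0.138).

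Guard cell genes were lower in dry than in humid air and after ABA than after the control spray (list medians -0.57 and -0.42). With an estimated correlation the former was called (adjusted p = 0.0403) and the latter was not (adjusted p = 0.490). The latter holds only against the control spray, where the list was raised. Against unsprayed gl1-1 with slide as a block its median was 0.16 (adjusted p = 0.979). A smaller share of guard cells against leaf tissue would lower the 818 genes at least 4-fold higher in guard cells than in leaves. Their median was 0.003 in dry air and 0.156 after ABA, while 0.5 times the list's shift is -0.287 and -0.208 (spread 0.144 and 0.134). These genes include phloem AHA3, so shifts between cell types of the fraction stay open. More mesophyll after ABA is argued against by the Calvin cycle list, which was lower too (median -0.425). Regulation of these genes in guard cells stays open and untested, since slide cannot be told apart from humidity, nor the slide of the control arrays from the control spray.

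Guard cell genes were higher in slac1-3 (list median 0.61, 6 of 15 up and 1 down, estimated adjusted p = 0.0218) and, by the preset correlation alone, in ost1-2 (0.38, 2 up and 0 down, estimated adjusted p = 0.147). In ost1-2 a larger share of guard cells against leaf tissue is argued against by the 818 genes (median -0.16, where 0.5 times the list's shift is 0.188, spread 0.104). Slide or scan day stays open too, since 1 ost1-2 array shared a slide with Ler (list median 0.271). In slac1-3 the 818 genes were at 0.075 (0.5 times the shift 0.306, spread 0.232). A larger share, regulation and gl1-1 effects cannot be told apart, and 0 slides or scan days held both genotypes. Whether the slide with 1 array of each mutant gave rise to the genes raised in both stays open. The 219 genes raised in slac1-3 had a median of 0.461 within the other slide (spread 0.1, 88.1 % higher), but on 1 ost1-2 array.

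Aquaporins were higher in dry than in humid air (list median 0.50). Leaf material would raise the 183 genes at least 4-fold lower in guard cells than in leaves, and their median was 0.148, where 0.5 times the list's shift is 0.252 (spread 0.082), which argues against leaf material for the whole rise. A part of it stays open, since 67.8 % of the 183 genes and the Calvin cycle list lay higher (list median 0.19, camera adjusted p = 0.00135, estimated adjusted p = 0.542). No single array accounts for the rise, since the lowest median with each of the 8 arrays left out was 0.444. Regulation by humidity stays open and untested, since slide and humidity cannot be told apart.

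Other splits of the same arrays were fitted to see whether an arbitrary grouping of arrays gives as many calls. Chance can be excluded where the share of such splits is under 0.05. For guard cells against leaves 1 of 35 splits, the real one, gave as many genes (13594, highest other 3366). For humidity it was 1 of 35 (3087, highest other 3). For ABA the replicate numbers pair the arrays, and the 8 splits that part every pair are too few for a share under 0.05 (7973, highest other 2486, and 3929 among the splits that leave pairs together). For both treatments 100 of the 280 splits that part every pair were drawn. There 5 gave as high a correlation (0.314, highest other 0.346), so chance is not excluded for it. As many differing genes came from 2 (5028, highest other 5484). Splits that kept the real grouping of 1 treatment gave 355 to 5484 and others at most 8. This count therefore cannot tell whether the responses differ. For genes called the same way it was 1 of 100 (1226, highest other 1), but 97 of the 99 others gave 0. Splits of the humidity arrays other than the real one call at most 3 genes, which bounds the shared count, so this says nothing on how far the treatments agree. For slac1-3 the 10 splits are too few for a share under 0.05. There 2 splits, the real one among them, gave as many genes or more (270, highest other 3845), and the highest, which puts slac1-3 replicate 3 with gl1-1 replicates 1 and 2, calls many times the real count and points to a structure of the samples other than genotype.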
